A study of Homo sapiens and Mus musculus with 15 samples.

How the data were processed

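The series holds 15 samples, of which 2 are poly(A)+ RNA-seq libraries of mouse embryonic fibroblasts and 13 are ChIP-seq samples of mouse fibroblasts and human breast cancer cell lines. The ChIP-seq samples were not analysed here, since the deposited table used here covers the RNA libraries. Per the labels' protocols, RNA went through poly(A) selection and into libraries made with a kit that keeps strand, and the fibroblasts grew at 3% oxygen. The deposited signal per gene is the number of reads in exons scaled to 10000000 mapped reads of the library, not divided by gene length, per the file headers. HOMER made these values with analyzeRepeats, counting exons on both strands and condensing transcripts to 1 entry per gene on mm9, per the file headers. Bowtie2, HOMER and mm9 are named in the submitters' processing notes, and their versions are not given in the sources used here. Read filters and the treatment of reads that map to several places are also not given in the sources used here.

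Because both strands were counted together, reads of overlapping antisense genes cannot be told apart, as for Xist and Tsix. Genes with near-identical copies or processed pseudogenes, such as Gapdh and ribosomal protein genes, can lose or share reads and are reported as uncertain. Of the genes that passed the expression filter, 24 have more than 1 genomic copy in the table. Gene symbols, transcript identifiers and coordinates were taken from the table itself, in which all columns of values could be mapped to a library by name (0 could not).

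Whole reads were recovered from the deposited signal. Each value was divided by the worth of 1 read, 0.461 in the WT library and 0.479 in the R172H library, and 100% of values came out whole within a tolerance of 0.05. The libraries thus held 21.7 M and 20.9 M mapped reads, and their 20 genes of highest mean took 14.1% and 10.5% of the reads in genes. The table lists 23954 genes. The design foresaw values per 10000000 from HOMER, so they were used as deposited, with a pseudocount of 10 for log2 ratios and for every count of genes past a fold. Log2 ratios on this scale understate differences of weakly expressed genes. Genes with a mean of at least 50 over both libraries passed the expression filter, which left 10315. Folds of single genes were computed from reads without a pseudocount. Their intervals are exact 95% Clopper-Pearson intervals of the reads in 1 library out of both, converted to a ratio. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A fold against 0 reads is given as "at least" against a floor of 3 reads per library. This floor leaves out counting error in the other library, and the lower limits of the exact intervals are smaller, 1183 rather than 1456 for Nos2.

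With 1 library per genotype no test across conditions was possible, no p-value is given, and the values describe these libraries. Gene lists, the rule for named genes, thresholds and most alternatives were fixed before the data were examined, and 34 lists were fixed in this way. For each list the median log2 ratio of members that passed the filter was placed among 10000 random lists of equal size, matched on mean expression in 20 bins. The interval of a list median comes from 1000 Poisson draws of the reads. Members at least 1.5-fold higher or lower were counted on the log2 scale with the pseudocount. Among these fixed lists, a few genes stand in more than 1 list, and no list shares more than 1 member with the others.

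Named genes were Trp53 and the 12 genes of highest and the 12 of lowest log2 ratio among genes that passed the filter. In each list, up to 4 passing members with the largest absolute log2 ratio were named too. Predicted genes without a symbol and small RNAs were left out of the highest and lowest. Kmt2a, Kmt2d, Kat6a and the HoxA genes were added because the study is known to concern them, and Xist and the Y-linked genes as a check of the sex makeup of the cultures. Any other gene named was chosen after its values were seen. A further 9 lists were chosen after the data had been seen. They are not independent of the fixed lists: a pair of them splits the hypoxia and glycolysis list, and others share members with fixed lists. Tap1, Psmb8 and B2m stand in the MHC class I list, and Ccl20 and Kdm6a in others.

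The alternatives were pseudocounts of 1 and 50, scaling to a median log2 ratio of 0, TMM factors, totals without the 20 genes of highest mean, no filter, a mean of at least 250, thresholds of 1.5-fold and 4-fold, and a counting interval wholly beyond 2-fold. Scaling to total reads in genes, leaving out X- and Y-linked genes, and counts of list members past 1.5-fold under the pseudocounts and scalings were added after the data had been seen. TMM factors were computed with edgeR 4.0.16 in R 4.3.3 from the recovered reads. All else was computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

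The procedure was tested on simulated libraries of 10326 genes with the depths and means of the R172H and WT libraries. Reads were drawn with Poisson noise alone, without biological or library-to-library variation. The rates below thus cover counting error only, and say nothing of false calls from such variation. All reads were recovered (100% of genes), and the intervals held the true ratio for 95.4% of genes. Of genes simulated with a 4-fold difference, 100% were called at least 2-fold different in the right direction, and 0% of genes simulated at 1.5-fold were. Of 9927 genes simulated without a difference, 0 were called. A list of 20 genes raised 1.5-fold lay at percentile 100, and 97.5% of lists of unaltered genes lay between percentiles 2.5 and 97.5. Simulated genes varied independently and most had no difference. The list values thus do not show how percentiles behave for lists in the real libraries.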

Results

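Poly(A)+ RNA was sequenced from primary mouse embryonic fibroblasts (MEFs), cells grown out of mid-gestation embryos and cultured here at 3% oxygen. One genotype was wild type (WT). The other was homozygous for the Trp53 R172H knock-in, a missense change in the DNA-binding domain of p53 that models a recurrent human tumour mutation. Each genotype was represented by 1 library, so n = 1 throughout and no difference had a replicate check. The WT library held 21.7 M mapped reads, of which 15922580 (73.4%) fell in exons of listed genes. The R172H library held 20.9 M, of which 15364328 (73.6%) did so. At least 1 read was found for 16367 genes in WT and 16895 genes in R172H. Values below are normalised read counts, in reads per 10000000 mapped reads, and each ratio carries an exact 95% counting interval. These intervals cover counting error only, and neither biological nor library-to-library variation. A gene with 0 reads was set against a floor of 3 reads, worth 1.38 in WT and 1.44 in R172H. Counts of genes past a fold used ratios with a pseudocount of 10, so a weakly expressed gene can fall short there although its printed fold lies just past 1.5. Coordinates are on mm9 and span the listed transcript.

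The comparison asked how the transcriptome of fibroblasts carrying only mutant p53 differed from that of fibroblasts with normal p53. Trp53 RNA itself (NM_001127233, chromosome 11, 69393861 to 69405375) was 1.33-fold higher in R172H (interval 1.25 to 1.42), at 1078 against 808. A point mutation need not alter the RNA level, so this value does not check the genotype label. Genes that p53 activates were lower in the R172H library, while interferon-response, secreted inflammatory, hypoxia and proliferation genes were higher. Of 10315 genes with a mean of at least 50, 789 (7.65%) were at least 2-fold higher in R172H and 297 (2.88%) at least 2-fold lower. The remaining 9229 genes lay within 2-fold. The libraries also differed in sex-linked RNA. Xist, the non-coding RNA that coats the inactive X chromosome of female cells, had 11964 reads in WT and 5 in R172H. Of the 2-fold genes, 31 of the 789 higher and 7 of the 297 lower ones lay on X or Y. Of all 10315 genes, 9982 lay outside X and Y. The higher genes stayed the larger group under every scaling tried, the narrowest split being 671 against 379 with TMM factors. These factors shifted R172H values by −0.12 on the log2 scale before the pseudocount was added. Ratios of genes with low R172H values thus moved by less.

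Genes activated by p53 were lower in R172H as a group. Of 38 p53-activated genes that passed the expression filter, 25 were at least 1.5-fold lower, 12 lay within 1.5-fold and 1 was higher. Their median log2 ratio was −1.03 (interval −1.14 to −0.99), at percentile 0 of 10000 random lists of equal size and matched expression. Of the 12 genes with the lowest ratios among all that passed, 4 belonged to this list. Ptprv, a receptor-type phosphatase gene, was at 427 in WT and 7.18 in R172H, 59.5-fold lower (35.9 to 107). Eda2r, an X-linked death-receptor family gene, was at 214 against 3.35, 63.8-fold lower (30.7 to 160). The gene listed as 9030617O03Rik was 91.2-fold lower (35.3 to 337), and Sulf2, a heparan sulfate endosulfatase gene, 12.9-fold lower (11.3 to 14.9).

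Several familiar p53 targets were picked after their values were seen. Cdkn1a (chromosome 17, 29230717 to 29237667), which encodes the cell-cycle inhibitor p21, was at 2839 in WT and 479 in R172H, 5.93-fold lower (5.54 to 6.34). Ccng1, encoding cyclin G1, was 9.47-fold lower (8.88 to 10.1). Mdm2, which encodes the ubiquitin ligase that degrades p53, was 2.73-fold lower (2.52 to 2.95), and the apoptosis gene Bax was 2.82-fold lower (2.53 to 3.13). Perp lay below the expression filter and had 125 reads in WT and 0 in R172H, at least 40.1-fold lower. With the pseudocount, the single member at least 1.5-fold higher was Fas, a death receptor gene, at 36.9 against 80.5, 2.18-fold higher (1.66 to 2.88) without it. Ddb2 was 1.54-fold higher (1.21 to 1.95) without the pseudocount, and passed 1.5-fold with a pseudocount of 1.

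**Figure D1:**
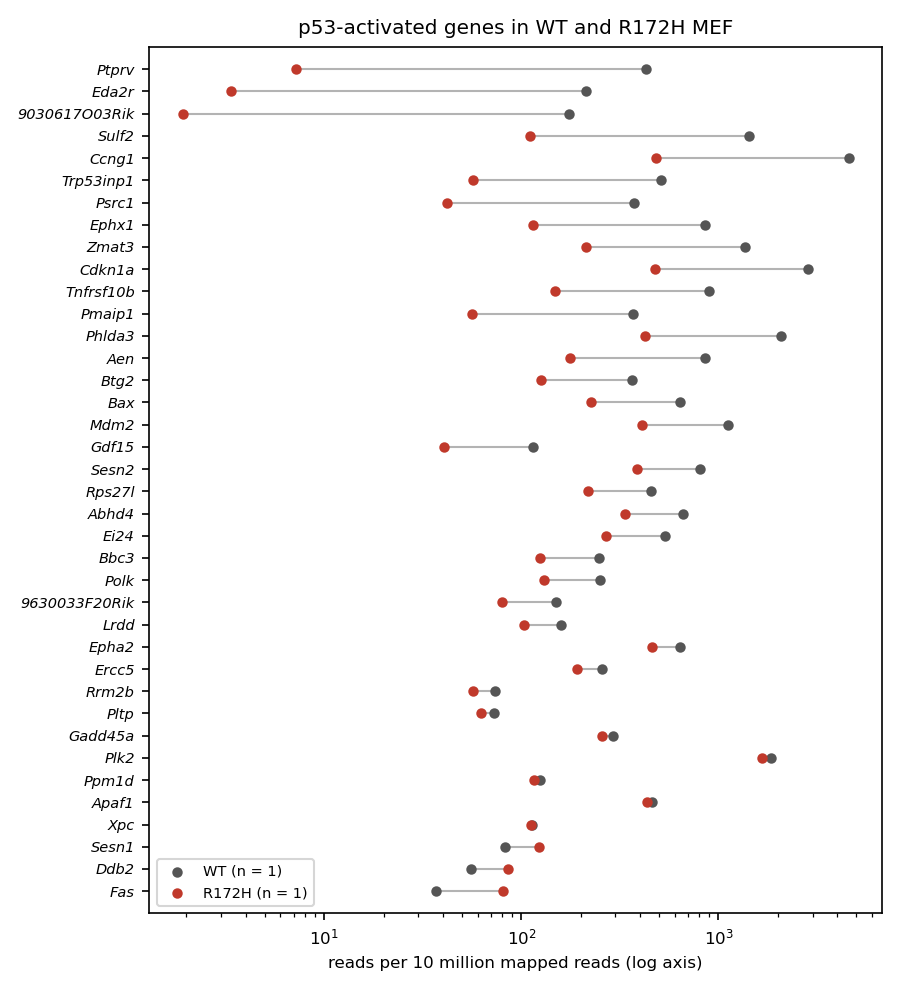
Normalised read counts (reads per 10000000 mapped reads, log axis) of the 38 p53-activated genes that passed the expression filter, with 1 point per library in grey for WT and in red for R172H and a line joining both. Most red points lie to the left of their grey partner, as for Ccng1 at 483 against 4577, and Fas lies the other way.

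Chromatin regulators that the study is known to concern are the histone methyltransferases Kmt2a (MLL1) and Kmt2d (MLL2) and the acetyltransferase Kat6a (MOZ). Kmt2a (NM_001081049, chromosome 9, 44611438 to 44689357) was at 1996 in WT and 3012 in R172H, 1.51-fold higher (1.45 to 1.57). Kat6a (NM_001081149, chromosome 8, 23970011 to 24053734) was at 993 and 1541, 1.55-fold higher (1.47 to 1.64). Kmt2d (NM_001033276, chromosome 15, 98662100 to 98701636) was at 3303 and 3710, 1.12-fold higher (1.09 to 1.16). None of these genes reached 2-fold. The 20 genes of the MLL/COMPASS methyltransferase complexes had a median log2 ratio of 0.22 (0.19 to 0.27), at percentile 94.9, inside the central 95% of random lists. Only Kmt2a and Kmt2e were at least 1.5-fold higher in that list, Kmt2e by 1.81-fold (1.72 to 1.91). Kmt2a fell short of 1.5-fold under 3 other scalings and with a pseudocount of 50, its log2 ratio of 0.59 being 0.47 with TMM factors, which left Kmt2e alone. The 15 histone acetyltransferase genes of the MYST and related families had a median of 0.30 (0.20 to 0.36), at percentile 94.5. Kat6a and Kat2b were the 2 members at least 1.5-fold higher, Kat2b by 1.76-fold (1.49 to 2.08). Kat6a also fell short under these 3 scalings, its log2 ratio of 0.63 being 0.51 with TMM factors.

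HoxA genes, a cluster of developmental regulators, were higher in R172H as a group. A link to the level of Kmt2a was not tested. Of 8 HoxA genes that passed the filter, 5 were at least 1.5-fold higher and none was that much lower, while 4 were so with TMM factors and 3 with a pseudocount of 50. Their median log2 ratio was 0.72 (0.59 to 0.80), at percentile 99.5. Random lists were drawn gene by gene, whereas Hox genes of a cluster are neighbours. The percentiles of Hox clusters thus do not allow for neighbours that shift together. Hoxa11 (chromosome 6, 52192104 to 52195809) was 2.15-fold higher (1.82 to 2.54), Hoxa2 1.93-fold (1.49 to 2.49), Hoxa9 1.83-fold (1.55 to 2.16) and Hoxa3 1.70-fold (1.52 to 1.90). Hoxa10 was 1.66-fold higher (1.45 to 1.91), Hoxa4 1.58-fold (1.21 to 2.07) and Hoxa5 1.48-fold (1.33 to 1.66). Hoxa7 was at 122 against 140, with an interval of the ratio from 0.966 to 1.36. Below the filter, Hoxa6 was 3.02-fold higher (2.15 to 4.33), while the intervals of Hoxa1 and Hoxa13 included equal levels. The HoxB genes had a median of 0.49 (0.40 to 0.64), at percentile 97.8. Of 8, 3 were at least 1.5-fold higher, or 2 with TMM factors and with a pseudocount of 50. Hoxb5 was 1.79-fold higher (1.48 to 2.17). The HoxC genes had a median of −0.27 (−0.43 to −0.14), at percentile 4.73. Of 6, 2 were at least 1.5-fold lower, or 3 with TMM factors, Hoxc5 by 1.81-fold (1.51 to 2.17). Of 4 HoxD genes, Hoxd13 alone was past 1.5-fold, at 1.63-fold lower (1.46 to 1.82), and the median was 0.17 (−0.03 to 0.33), at percentile 54.5. The HoxC median became 0.10 without the filter, and the HoxD median −0.68 with a mean of at least 250.

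**Figure D2:**
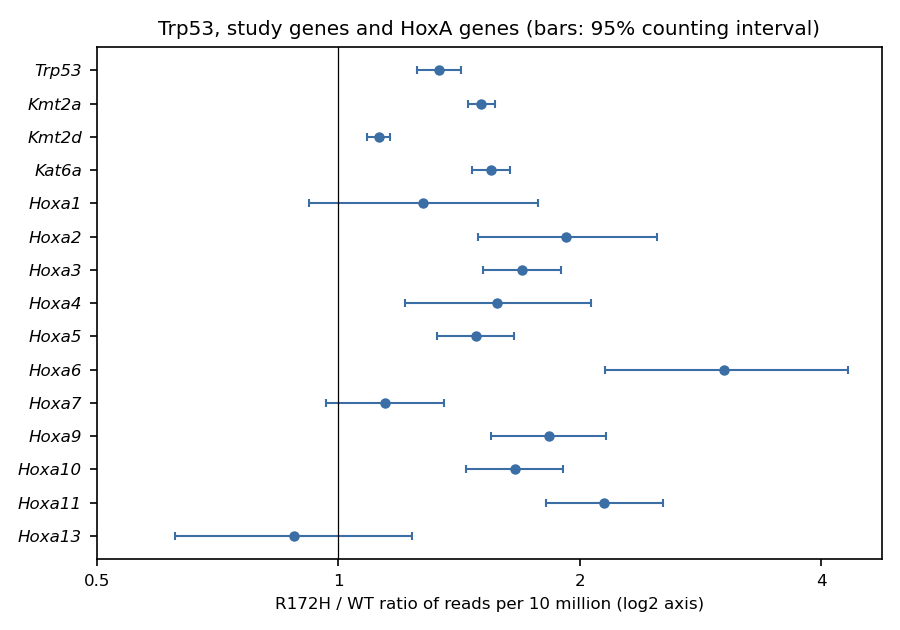
Ratio of normalised read counts, R172H over WT (log2 axis), of Trp53, Kmt2a, Kmt2d, Kat6a and the 11 HoxA genes, with points for the ratio of 1 library to 1 library and bars for the exact 95% counting interval. Kmt2a and Kat6a lie near 1.5, Kmt2d at 1.12, and Hoxa6 and Hoxa11 farthest to the right at 3.02 and 2.15.

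Interferon-response genes, the antiviral programme that type I interferons switch on, made up 8 of the 12 genes with the highest ratios. All 23 members that passed the filter were at least 1.5-fold higher in R172H. Their median log2 ratio was 5.10 (4.87 to 5.21), at percentile 100 of the random lists, and 3.37 with a pseudocount of 50. Without the pseudocount, and with the 1 member absent from WT at its bound, it was 6.75. Ifit1 was at 3.23 in WT and 2488 in R172H, 770-fold higher (374 to 1917), and Oasl2 was 602-fold higher (292 to 1499). Isg15 (chromosome 4, 155573533 to 155574927), a ubiquitin-like modifier, was at 16.1 and 3480.1, 216-fold higher (155 to 310). Ifit3 was 176-fold higher (114 to 289), and the interferon regulatory factor gene Irf7 108-fold (75.2 to 162). Markers of macrophages and blood cells stayed below the filter in both libraries and summed to 29.1 in WT and 92.9 in R172H over 18 genes.

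Genes outside that list also stood among the 12 highest. Nos2, encoding inducible nitric oxide synthase, had 0 reads in WT and 4205 in R172H, at least 1456-fold higher. Tmem163 had 0 and 1249 reads, at least 432-fold higher. The complement gene C3 had 3 reads in WT and 1567 in R172H, a 542-fold ratio (185 to 2633). Cp, encoding the copper carrier ceruloplasmin, was at 7.84 and 999, 127-fold higher (79.3 to 219). Secreted inflammatory factors were also higher. Of 15 that passed, 13 were at least 1.5-fold higher and 1 at least 1.5-fold lower, or 2 lower under 3 other scalings, the median log2 ratio being 2.38 (2.21 to 2.58), at percentile 100, or 1.45 without the filter. Il6 was 68.6-fold higher (40.7 to 126), the neutrophil chemokine gene Cxcl1 44.7-fold (33.5 to 61.1) and Cxcl5 23.7-fold (20.8 to 27.1). Ccl5 had 1 read in WT and 311 in R172H, a 323-fold ratio with an interval from 57.5 to 12796. Igfbp5 and Serpine1, named after their values were seen, were lower by 1.71-fold (1.65 to 1.77) and 1.47-fold (1.44 to 1.49), and Serpine1 passed 1.5-fold only under those scalings.

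Cell-cycle genes were higher in R172H. Of 22 G2/M genes, 21 were at least 1.5-fold higher, with a median log2 ratio of 1.03 (0.99 to 1.10), at percentile 100. Mki67, encoding the proliferation marker Ki-67, was at 2737 in WT and 7757 in R172H, 2.83-fold higher (2.75 to 2.92). The mitotic kinase genes Bub1 and Aurkb were 2.82-fold (2.51 to 3.17) and 2.70-fold higher (2.43 to 3.00). Of 21 G1/S genes that passed, 16 were at least 1.5-fold higher, or 14 under 3 other scalings. Their median was 0.81 (0.72 to 0.89), at percentile 100. Rad51, the homologous recombination gene, was 2.60-fold higher (2.18 to 3.12), and Tyms, encoding thymidylate synthase, 2.43-fold (2.15 to 2.76). Inhibitors of cyclin-dependent kinases other than Cdkn1a were higher too, 4 of 6 by at least 1.5-fold, with a median of 0.76 (0.66 to 0.83), at percentile 99.5. Cdkn1c, encoding p57, was 3.10-fold higher (2.74 to 3.53), and Cdkn2a, which encodes p16 and p19Arf, 1.66-fold (1.58 to 1.74). Cdkn2b, named after its value was seen, was 1.61-fold lower (1.53 to 1.70).

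Hypoxia and glycolysis genes were higher although both cultures were grown at 3% oxygen. Of 18 members, 15 were at least 1.5-fold higher, or 13 with TMM factors. Their median log2 ratio was 1.31 (1.21 to 1.36), at percentile 100. Car9, encoding carbonic anhydrase IX, was at 10.6 in WT and 442 in R172H, 41.6-fold higher (27.6 to 66.0). The prolyl hydroxylase gene Egln3 was 13.1-fold higher (11.9 to 14.4), Adm 9.79-fold (8.88 to 10.8) and Ndrg1 8.04-fold (7.45 to 8.69). Cholesterol synthesis genes went the other way. Of 19 that passed, 9 were at least 1.5-fold lower, or 14 with TMM factors, and none was that much higher, with a median of −0.57 (−0.71 to −0.55), at percentile 0. Mvd was 2.24-fold lower (1.97 to 2.54), Sc4mol 2.21-fold (2.02 to 2.42) and the LDL receptor gene Ldlr 2.08-fold (1.98 to 2.18). Hmgcs1 was listed at 0 in both libraries on an unplaced contig, and was not measured.

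Markers of the fibroblast lineage and of related mesenchymal fates were mixed. Of 24 fibroblast and extracellular matrix genes, 7 were at least 1.5-fold lower, or 12 with TMM factors, and 4 at least 1.5-fold higher. The median log2 ratio was −0.39 (−0.42 to −0.37), at percentile 0.01, while the mean was 0.04. Postn, encoding the matrix protein periostin, was 2.19-fold lower (2.13 to 2.26). In contrast, the proteoglycan genes Dcn and Lum were 17.0-fold (13.5 to 21.7) and 10.8-fold higher (7.62 to 15.9), and the growth factor receptor gene Pdgfra was 7.66-fold higher (7.11 to 8.26). Smooth muscle and myofibroblast genes had a median of −0.50 (−0.53 to −0.48), at percentile 0.04, with 6 of 12 at least 1.5-fold lower, Myh11 by 2.54-fold (2.17 to 2.99), and 1 at least 1.5-fold higher only with a pseudocount of 1. Only 3 skeletal muscle genes passed, with a median of −0.79 (−0.95 to −0.63), at percentile 0.57, and Acta1 was 10.9-fold lower (9.72 to 12.2). Without the expression filter this median was 0.068, the log2 ratio of a gene with 0 reads in WT and 1 in R172H. Of 6 cartilage and bone genes, 3 were at least 1.5-fold lower, or 4 with TMM factors, and 1 higher. Their median was −0.54 (−0.62 to −0.47), at percentile 0.16. It became 0.068 without the filter, again the value of a gene with 0 reads in WT and 1 in R172H. Acan and Col2a1, which encode cartilage matrix proteins, were 4.04-fold (3.35 to 4.89) and 3.32-fold lower (3.10 to 3.55), whereas the cartilage regulator gene Sox9 was 2.22-fold higher (2.02 to 2.46). Col10a1, a collagen gene of hypertrophic cartilage, was at 1024 against 21.1, 48.6-fold lower (36.1 to 67.1), and the elastin gene Eln was 23.9-fold lower (17.5 to 33.3). The other autosomal genes among the 12 lowest were Klhl30, Ano3, Dsp and Fam212b, of which Ano3 had 252 reads in WT and 0 in R172H, at least 80.9-fold lower.

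Markers of other cell types were sparse. None of 12 erythroid genes passed the filter, and they summed to 10.1 in WT and 11.5 in R172H. Flt1 was the single endothelial marker to pass, with a log2 ratio of −0.77 (−0.88 to −0.66), at percentile 4.92. Krt19 was the single epithelial marker, with a log2 ratio of 2.90 (2.75 to 3.07), at percentile 98.9. Without the pseudocount it was 7.88-fold higher in R172H (7.05 to 8.83). Without the filter, the endothelial and epithelial medians were 0.15 and 0.21. Of 4 neural and glial genes that passed, Map2 was 2.67-fold lower (2.42 to 2.95) and Tubb3 1.55-fold higher (1.43 to 1.69), a size it missed under 3 other scalings and with a pseudocount of 50, with a median of −0.08 (−0.13 to −0.02), at percentile 36.0. The 4 adipocyte genes that passed had a median of 0.55 (0.33 to 0.75), at percentile 92.2, with Fabp4 and Lpl higher and Scd1 lower by at least 1.5-fold. With a mean of at least 250 the adipocyte median was −0.88.

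The medians of the signalling and stress lists lay within the central range of random lists. In most of these lists, members past 1.5-fold went both ways. Immediate early genes had a median log2 ratio of 0.33 (0.16 to 0.40), at percentile 97.2, with 4 of 12 at least 1.5-fold higher and 1 lower, or 2 lower under 3 other scalings. Ier3 was 7.51-fold higher (6.94 to 8.13) and Fosl1 4.60-fold (4.18 to 5.08). TGF-beta targets had a median of −0.06 (−0.11 to −0.04), at percentile 26.2. Of 14, 5 were at least 1.5-fold lower, or 6 under 3 other scalings, and 2 higher. The ligand gene Tgfb2 was 5.22-fold lower (4.68 to 5.84), and Id2 was 3.20-fold higher (2.76 to 3.72). The unfolded protein and amino acid response list had a median of −0.10 (−0.16 to −0.05), at percentile 17.7, with 5 of 17 at least 1.5-fold lower and 2 higher, or 7 and 0 with TMM factors, and Chac1 was 3.57-fold lower (3.08 to 4.14). Oxidative stress genes of the Nrf2 pathway had a median of −0.01 (−0.11 to 0.07), at percentile 30.4, with Gstm1 the 1 of 13 past 1.5-fold with the pseudocount, at 4.03-fold higher (3.16 to 5.19), and 1 other lower by as much as 1.5-fold with TMM factors.

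Lists fixed as references lay near 0, with exceptions. Proteasome genes had a median log2 ratio of 0.02 (−0.00 to 0.07), at percentile 37.4, with none of 31 past 1.5-fold, or 1 lower with TMM factors, and the sign of this median flipped under 3 other scalings. The sign of the imprinted list's median of 0.05 (−0.01 to 0.19), at percentile 52.7, flipped under the same scalings, with 6 of 19 genes at least 1.5-fold higher and 2 lower, or 3 and 3 with TMM factors. Its members Nnat and Peg3 were 3.41-fold (2.86 to 4.09) and 2.32-fold higher (2.16 to 2.48), and Igf2r was 2.16-fold lower (2.09 to 2.23). Ribosomal protein genes had a median of −0.04 (−0.07 to 0.00) and a mean of 0.04, at percentile 16.8 for the median. Of 39 such genes, Rplp0, Rpl3 and Rpl30 were at least 1.5-fold higher, and 3 others were lower by as much with TMM factors and 1 under each of 2 other scalings and with a pseudocount of 1. These values are uncertain because processed pseudogenes can share reads, which was not tested. The 4 replication-dependent histone genes that passed had a median of −0.25 (−0.40 to −0.08), at percentile 8.25, with 1 at least 1.5-fold lower, or 0 with a pseudocount of 50, and such RNAs mostly lack the poly(A) tail that was selected for. Housekeeping genes had a median of 0.32 (0.21 to 0.38), at percentile 98.1, with 5 of 14 at least 1.5-fold higher, or 3 higher and 1 lower with TMM factors. B2m, a subunit of MHC class I, was the highest of them at 4.01-fold (3.88 to 4.16), and Gapdh, which also has many pseudogenes, was low and uncertain in both libraries at 59.5 and 129.8.

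Sex-linked genes differed between the libraries. Xist (chromosome X, 100655712 to 100678572) was at 5518 in WT and 2304-fold lower in R172H (987 to 7098). Tsix overlaps Xist on the opposite strand, had 1308 and 0 reads, and could not be told apart from it because both strands were counted together. The Y-linked translation factor gene Eif2s3y had 0 reads in WT and 520 in R172H, at least 180-fold higher. Kdm5d and Uty had 1 read each in WT against 422 and 397 in R172H, with ratios of 438 (78.2 to 17349) and 412 (73.6 to 16324). Ddx3y had 21 and 925 reads, a 45.7-fold ratio (29.7 to 74.2). Sry, Zfy1 and Zfy2 had 0 reads in both libraries, which allows up to 1.38 in WT and 1.44 in R172H. The 6 sex-linked genes that passed had a median log2 ratio of 4.30 (4.15 to 4.41), at percentile 100, with 4 higher and 2 lower, and 6.50 with absent genes at their bound. With a mean of at least 250 it was −7.37. Sex-linked RNA differed together with genotype between these libraries, beside every gene group above.

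**Figure D3:**
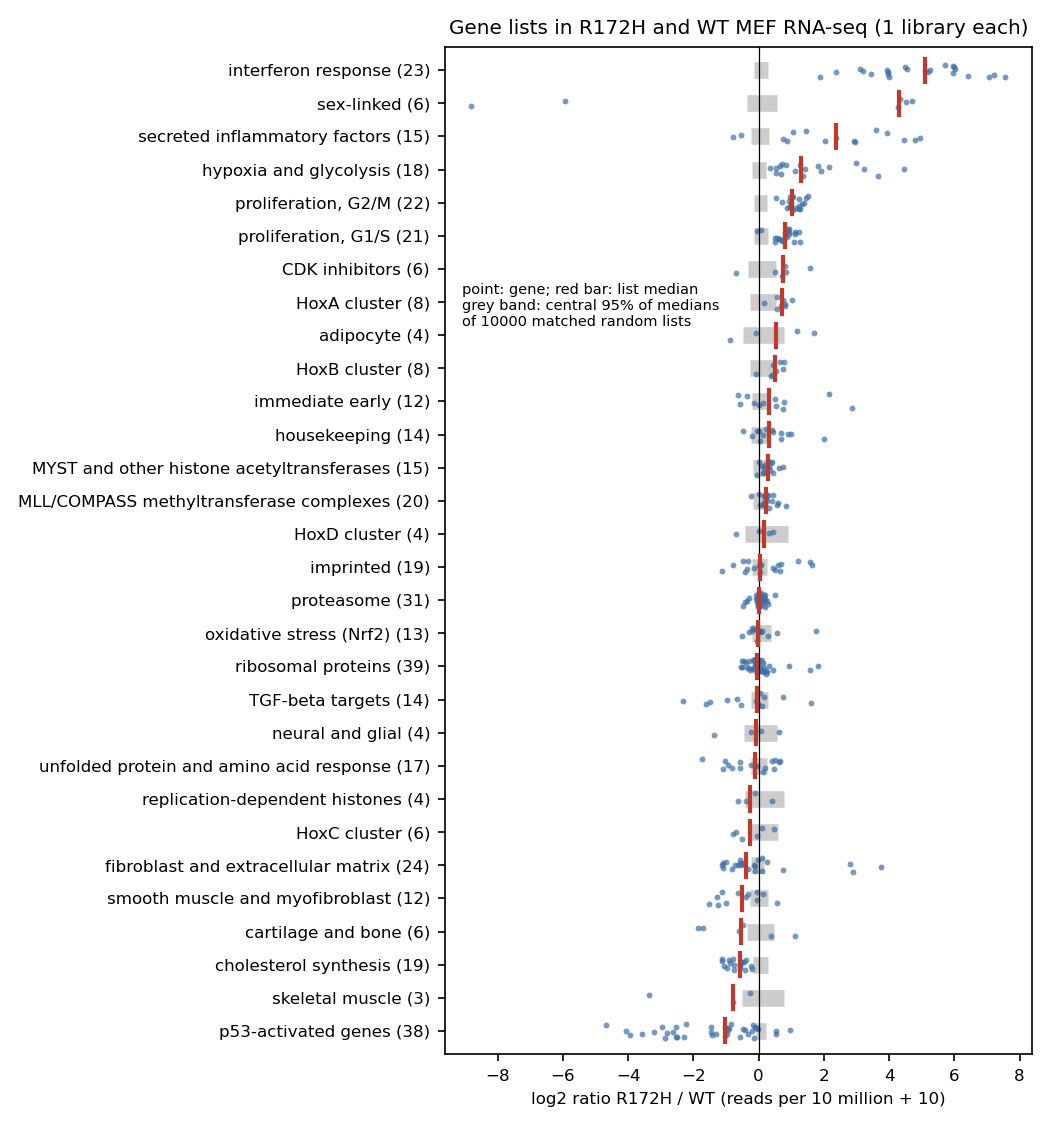
Log2 ratio of R172H over WT (reads per 10000000 plus a pseudocount of 10) for each gene that passed the expression filter, by list, with 1 point per gene, a red bar at the list median, and a grey band over the central 95% of medians of 10000 matched random lists. Interferon-response genes lie farthest right with a median of 5.10, p53-activated genes lie left of their band with a median of −1.03, and lists with fewer than 3 such genes are left out.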

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

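Scaling to total reads in genes, leaving out X- and Y-linked genes, and counts of list members past 1.5-fold under each setting were chosen after the data had been seen, and all other alternatives before. Under all 12 alternatives more genes were higher than lower in R172H. The counts of higher and lower genes were 1190 and 385 without a filter, 365 and 141 at a mean of at least 250, 1600 and 804 at 1.5-fold, 262 and 55 at 4-fold, and 758 and 290 without X- and Y-linked genes; fewer or more genes enter by construction. With a pseudocount of 50 the median log2 ratios were −0.90 for p53-activated genes, 0.55 for HoxA, 0.94 for G2/M, 0.69 for G1/S, 1.86 for secreted inflammatory factors, 3.37 for interferon response, 1.17 for hypoxia and −0.55 for cholesterol synthesis, and with a pseudocount of 1 interferon response reached 6.65. With TMM factors they were −1.15 for p53-activated genes, 0.10 for MLL/COMPASS, 0.18 for histone acetyltransferases, 0.91 for G2/M, 0.69 for G1/S and 1.19 for hypoxia, and Trp53 was at 0.29. Scaling to the median ratio gave 0.16 for MLL/COMPASS and 0.96 for G2/M, and totals without the 20 genes of highest mean gave 0.16 and 0.97. Without a filter, secreted inflammatory factors were at 1.45 and interferon response at 4.54. At a mean of at least 250, p53-activated genes were at −1.45, secreted inflammatory factors at 1.56, interferon response at 5.44, hypoxia at 1.19 and cholesterol synthesis at −0.76. The sign of the median reversed for skeletal muscle and for cartilage and bone, both at 0.068 without a filter, where members with few reads enter. That value is the log2 ratio of a gene with 0 reads in WT and 1 in R172H, so both reversals rest on barely detected members. It also reversed for sex-linked genes, at −7.37 with a mean of at least 250, where fewer members remain. The medians of HoxC, HoxD, endothelial, adipocyte, Nrf2, proteasome and imprinted genes, which lay within the central range of random lists, also took the other sign under at least 1 alternative. Of the comparisons with an alternative, 533 for named genes stayed within the counting interval and 207 moved. This interval has no pseudocount, and it was extended to the main value where that lay outside. Genes with 0 reads in both libraries counted as staying. For lists, 178 stayed within the interval of the median and 74 moved. Counts of list members past 1.5-fold stayed within 1.5 times in 283 comparisons and moved further in 37. Stmn2 changed sign with TMM factors and Hoxd12 under 3 scalings, both near equal levels. The cause of these moves was not tested beyond the construction of each alternative. Alternatives on the choice of transcript were not run because the table has 1 entry per gene, and a count test on the recovered reads has no replicates from which to estimate a spread. No paired analysis was possible because each genotype has 1 library. Depth limits genes at 0 reads, whose level is below 1.38 in WT and 1.44 in R172H.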

Other observations

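The gene lists in this part were chosen only after the data had been seen. A list chosen in this way can lie far out among random lists by that choice, so its percentile is descriptive only. The tests of mixed male cells, autosomal effects of sex, blood cells, culture differences and glycolysis were chosen only after the result was seen. The direction predicted for escape genes was written before their result, but their list was not among the fixed ones. Genes that present antigen on MHC class I, of which Tap1 and Psmb8 also stand in the interferon list and B2m in the housekeeping list, were higher in the R172H library. Of 18 that passed the filter, 17 were at least 1.5-fold higher, with a median log2 ratio of 2.47 (counting interval 2.35 to 2.64), at percentile 100 of 10000 matched random lists. The peptide transporter gene Tap1 was 10.2-fold higher (8.35 to 12.5) and the class I gene H2-K1 7.78-fold (7.20 to 8.42), the latter uncertain because class I genes are near-identical and vary between strains. Of class II genes only H2-Ab1 passed, with 4 reads in WT and 587 in R172H, while the class II activator gene Ciita had 4 and 6 reads and Cd74 had 2 and 9. H2-Ab1 set the class II value of 4.62 (4.38 to 4.84), at percentile 99.4. NF-kB pathway genes and targets had a median of 1.63 (1.53 to 1.73), at percentile 100, with 12 of 16 at least 1.5-fold higher, and 1.68 with the 3 genes absent from WT at their bound. Nfkbia, the inhibitor that NF-kB itself induces, was 5.63-fold higher (5.12 to 6.20), and the acute-phase gene Saa3 had 0 reads in WT and 872 in R172H, at least 302-fold higher. Interferon receptors and sensors had a median of 0.38 (0.34 to 0.44), at percentile 98.6, with 6 of 14 at least 1.5-fold higher.

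Notch pathway genes, a list chosen after the data had been seen, were lower in the R172H library. Their median log2 ratio was −0.68 (−0.82 to −0.59), at percentile 0. Of 12 that passed, 6 were at least 1.5-fold lower and 2 at least 1.5-fold higher. The ligand gene Jag1 was 8.40-fold lower (7.52 to 9.41), and the target genes Hey2 and Nrarp were 14.5-fold (9.00 to 24.8) and 22.3-fold lower (11.9 to 47.2). Heyl had 178 reads in WT and 0 in R172H, at least 57.1-fold lower. Notch1 was 2.25-fold lower (2.10 to 2.42), whereas Notch2 was 1.65-fold higher (1.58 to 1.73) and Rbpj, the DNA-binding partner of Notch, 2.23-fold higher (2.08 to 2.40).

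Xist reads in WT and Y-linked reads in R172H are consistent with cultures from embryos of different sex, and the 5 X-linked genes known to escape inactivation had a median log2 ratio of −0.36 (−0.44 to −0.32), in the direction that a single X would give. Of these, Eif2s3x alone was at least 1.5-fold lower, and percentile 3.20 lies inside the central 95% of random lists. Male cells mixed into the WT culture would account poorly for its 21 Ddx3y reads, since they would bring 30.4 reads of Eif2s3y, Kdm5d and Uty where 2 were observed (upper 95% limit 7.22). Without X- and Y-linked genes, 758 genes were at least 2-fold higher and 290 lower. An effect of sex on autosomal genes and an effect of genotype cannot be told apart with 1 library per genotype and a different sex in each.

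The interferon response in R172H was weighed against other sources. Markers of blood cells and macrophages summed to 92.9 in R172H, 2.67% of the level of Isg15, and to 29.1 in WT. These levels argue against such cells holding most of the interferon-response RNA. The sum was higher in R172H, so the presence of a few such cells in that culture is not excluded. Infection or foreign nucleic acid in that culture, or another culture difference, may be the source as well as genotype, and these cannot be told apart with 1 culture of each. Reads of interferon ligand genes summed to 16 in R172H and 12 in WT, with none of 10 genes past the filter. Ifnz held 10 and 12 of them, while Ifna4 had 4 and Ifnb1 2 reads in R172H against 0 in WT, too few to tell a difference at this depth.

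Hypoxia and glycolysis genes were higher in R172H at the same labelled oxygen. A shift of glycolysis alone was argued against by splitting this same list of 18 after its values were seen, so the split restates the list rather than testing it anew. Its 9 members outside glucose metabolism, among them Car9, Egln3, Adm and Ndrg1, had a median log2 ratio of 2.17 (2.07 to 2.27), at percentile 100 with 8 at least 1.5-fold higher. The 9 glucose metabolism genes, which are glycolytic enzymes, the transporter gene Slc2a1 and the kinase gene Pdk1, had 0.72 (0.70 to 0.76), at percentile 99.97 with 7 higher. A candidate explanation is lower oxygen at the cells in a denser R172H culture, which cannot be told apart from an effect of genotype because the labels give 3% oxygen for both cultures and no density.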
